A study of Arabidopsis thaliana with 6 samples.

How the data were processed

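RNA of 6 Arabidopsis root samples, 3 of whole roots and 3 of sorted root cells, was hybridised to 1 Affymetrix array each. Per the labels' protocols, RNA was extracted with a column kit for small samples and amplified in 2 cycles before biotin labelling, in the same words for both groups. The deposited values are signal intensities on a linear scale, made with MAS5 per the submitters' processing notes; the version, the target of the scaling and the detection calls are not given in the sources used here. All values were positive, and the mean of each array after trimming 2% at each end was 250.02 or 250.03, so the arrays were taken as already scaled and used as deposited. Their medians ranged from 74.9 to 91.4.

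Of 22810 probe sets, 64 are controls, 13513 pair with 1 gene in the platform annotation, 503 with several and 8730 are not listed there. Those of the last kind are unnamed here, not without a gene. Of the 13513, 13436 were matched to the reference gene table (assembly TAIR10.1), which was used for names only. Of 439 entries in the 25 gene lists fixed before the data were examined, 67 had a probe set and 51 were tested, so 7 lists had the 4 tested members that a list test needed. Of these lists, those for jasmonate, hypoxia and phloem genes had no tested member, and those for non-hair epidermis and suberin had no probe set. A further 27 lists, of which 26 could be tested, were drawn up after the annotation had been read, when values of some organelle genes and control probe sets had already been seen. A planned list of cytosolic ribosomal proteins was not made, since no table used here gives gene titles.

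Control probe sets and the dimmest 40% of the others, by mean over all 6 arrays, were left out, which left 13647. Log2 intensities were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend of variance on mean; sorted cells minus whole roots), and Benjamini-Hochberg adjusted p-values under 0.05 were called. Gene lists were tested with limma's camera at a preset correlation of 0.01 within a list, two-sided, adjusted over the fixed lists and over the later lists separately. Camera with an estimated correlation and fry were alternatives; fry tests whether the genes of a list move one way on balance and does not compare them with other genes. Other values were computed with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and drawn with matplotlib 3.10.9. Differences between 3′ and 5′ control probe sets were compared by an exact two-sided permutation test.

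In simulated data with 200 of 13647 probe sets changed, the fit recovered 0% of changes of 0.5, 12.5% of changes of 1 and 65.8% of changes of 2 on the log2 scale. It made 57.8 calls per run there, of which 6 were false, or 10.4%, above the nominal rate, and called no list. Simulated probe sets were drawn independently, whereas the estimated correlation in the data was 0.73 for the wound list and 0.86 for the plastid list. Far fewer were changed than the 55.4% of tested probe sets called in the data. The shares recovered, the false share of 10.4% and the lack of called lists therefore do not carry over to the data. The false share among the calls in the data is not known.

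The genes named were set by a rule fixed before the data were examined: the 10 largest rises and 10 largest falls among called probe sets with 1 gene and no overlap between the groups, and from each list up to 4 called members with the largest change and up to 2 others with the highest mean; all iron genes with a probe set could be named. A gene with several probe sets is represented by the brightest. The text prints values for part of the genes that this rule selects, and the counts of genes that kept a call cover all of them. Where every array of a group read no higher than the brightest of 27 control probe sets for bacterial genes on that array (10.4 to 57.4), the difference is given as at least N-fold. It sets the brighter group's mean log2 value against the higher of that level and the gene's own signal on each array of the dimmer group. This level was chosen after the control values had been seen.

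Alternatives were quantile normalization, median centring, offsets of 16 and 64 before the log, no filter and a 60% filter on dim probe sets, no variance trend, robust variance, the replicate number as a block, each array left out in turn, and a 2-fold threshold. Array quality weights were added after seeing the data.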

Results

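The study asked how protoplasting and passage through a fluorescence-activated cell sorter change root transcript levels, above all those of genes regulated by iron. Columbia seedlings of Arabidopsis thaliana, 6 days after germination, had spent 24 hours on medium in which 0.3 mM of the iron chelator ferrozine took the place of ferrous sulfate. RNA came either from intact whole roots (3 arrays) or from root protoplasts that had all been collected after sorting (3 arrays), on 1 Affymetrix array per sample. Each array gave 22810 MAS5 signal intensities, and the number of arrays limits the precision. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Whole-root arrays correlated at 0.966 to 0.974 with each other (Pearson's r of log2 values across 13647 probe sets, which are not independent replicates) and sorted-cell arrays at 0.876 to 0.948. Correlations between the groups lay at 0.514 to 0.666. The median SD of a probe set was 0.18 (log2) among whole roots and 0.37 among sorted cells.

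All 5 tested early wound genes, of 32 listed, and all 4 tested detoxification genes, of 27 listed, were higher in sorted cells than in whole roots. So were 60 of 65 tested plastid genes and all 13 tested genes listed as mitochondrial. The 5 tested SWEET sugar transporter genes, of 14 with a probe set, and 7 of 11 tested nuclear photosynthesis genes were lower. With an estimated correlation no such list passed: the limma camera adjusted p was 0.276 for the wound and detoxification lists, 0.716 for the plastid, mitochondrial and SWEET lists and 0.795 for nuclear photosynthesis. ORA47, a transcription factor gene of the jasmonate pathway, stood at 11.8 ± 8.92 in whole roots and 1583 ± 269.6 in sorted cells (mean ± SD of intensities, n = 3 each; log2 difference 7.57, SE 0.70; limma adjusted p = 5.25e-05), with 2 of 3 whole-root arrays above the background level, the brightest bacterial control probe set of each array. In the other direction AT1G74460, which codes for a GDSL-type lipase family protein, stood at 2248 ± 119 in whole roots and 45.8 ± 0.297 in sorted cells (log2 difference -5.61, SE 0.18; limma adjusted p = 1.93e-06), with 2 of 3 sorted-cell arrays above that level. Of the 13647 probe sets tested, 7564 differed by limma, 3377 higher and 4187 lower in sorted cells, and 5388 of these by at least 2-fold. The groups did not overlap for 8903 tested probe sets, or 65.2%, where chance gives 10%.

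Some control probe sets for the ends of housekeeping transcripts differed between the groups as well, and others did not. The log2 difference between the 3′ and 5′ probe sets of actin was 1.69 ± 0.145 in whole roots and 4.33 ± 1.1 in sorted cells, and that of GAPDH 0.757 ± 0.133 and 3.66 ± 1.36 (mean ± SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). Sorted-cell replicate 1 had the largest differences, 5.53 for actin and 5.12 for GAPDH. In a second pair of actin probe sets the difference was 5.13 ± 0.525 in whole roots and 5.13 ± 0.259 in sorted cells, and in a second pair for ubiquitin 2.64 ± 0.266 and 3.03 ± 0.511, with overlapping groups (exact two-sided permutation p = 1 and 0.5). The 5′ probe set of that actin pair was dim, at 75.8 ± 26.7 in whole roots and 87.2 ± 12.4 in sorted cells. That of the first actin pair went from 1701 ± 287 to 371 ± 237. Probe sets for the middle of these transcripts were lower in sorted cells without overlap. They stood at -1.38 and -1.40 (log2) for actin, -0.97 for GAPDH and -0.99 for ubiquitin.

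**Figure D1:**
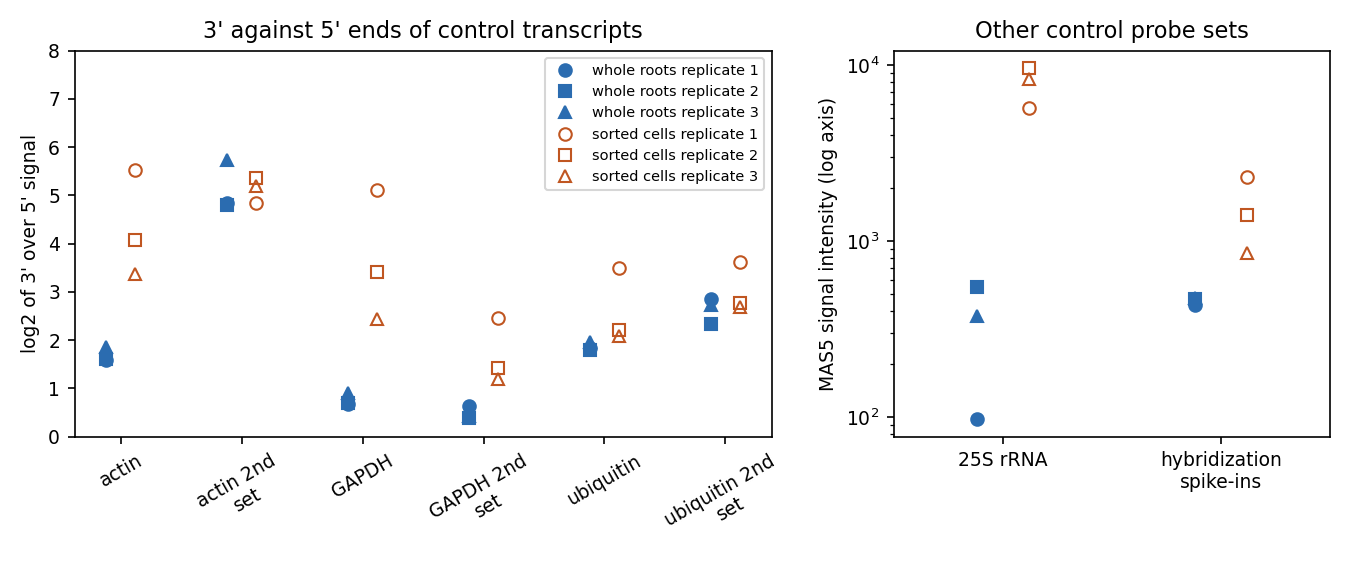
Left, log2 of the 3′ over the 5′ signal of control transcripts on each array; right, signal intensity (log axis) of the 25S ribosomal RNA probe set and the geometric mean of 18 hybridization spike-in probe sets, with a shape for each replicate. For actin the sorted-cell arrays (open) lie at 3.37 to 5.53 and the whole-root arrays (filled) at 1.85 or lower; in the second sets of actin and ubiquitin the groups overlap.

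Among the 10 genes with the largest rises were nad4, listed as mitochondrial, at 7.98 on the log2 scale, and the plastid genes rpoC1, matK and rpl20, at 6.87, 6.81 and 6.74. The others were ORA47, the calmodulin-like gene CML37 (7.55), AT3G02840 (7.27), AT1G48070 (7.19), AT2G01300 (7.03) and AT3G01830. Of 3 whole-root arrays, 2 read above the background level for nad4, rpoC1, matK and ORA47, and 1 for CML37, AT3G02840, AT1G48070 and AT2G01300. The whole-root signal of AT3G01830 lay at or under that level on every array, so its rise is given as at least 19.9-fold. The largest falls held 2 peroxidase genes, AT5G14130 (-6.45) and AT2G35380 (-6.04), and AT4G24140 (-6.43), AT3G50400 (-5.79), AT4G38080 (-5.74), AT1G74460 and AT5G12420 (-5.49). Apart from AT1G74460, these falls had 1 of 3 sorted-cell arrays above the background level, and such differences are imprecise in size. AT5G37690 was at least 21.2-fold lower, AT1G14120 at least 7.35-fold lower and TPS-CIN, a terpene synthase gene of 1,8-cineole, at least 16.4-fold lower; the probe set of TPS-CIN may also read a near-identical neighbouring copy. With 64 added to every intensity before the log, ORA47 stood at 4.44, CML37 at 3.58 and AT5G14130 at -3.45, all passing.

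All 5 tested genes of the early wound and elicitor list rose, over all genes and adjusted over the list alone, with a median log2 difference of 4.22. CML37 led the list, STZ, a zinc-finger repressor induced by many stresses, rose from 32.4 ± 5.74 to 2394 ± 582, and WRKY22 and WRKY53, regulators of defence genes, rose by 4.22 and 3.78 on the log2 scale, WRKY22 with 2 of 3 whole-root arrays above background. In the oxidative stress and detoxification list 4 of 4 tested genes rose over all genes and adjusted over the list alone, with a median of 2.35. They were the glutathione transferase genes GSTU25 (3.73) and GSTU22 (1.81), whose families hold close copies, and the glycosyltransferase genes UGT73B4 (2.89) and UGT73B5 (1.26). By limma's camera the adjusted p was 0.00084 for the wound list and 0.00278 for the detoxification list, and with an estimated correlation the adjusted p was 0.276 for each. Over all alternatives the adjusted p ran from 0.000146 to 0.276 for the wound list and from 0.000741 to 0.276 for the detoxification list.

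Calcium and defence lists drawn up after the annotation had been read held further rises. The 5 tested genes of the wound list recur in them, CML37 among calmodulin-like genes and STZ, WRKY6, WRKY22 and WRKY53 in the immunity list. Tests of these lists are therefore not separate from that of the wound list. Of 6 tested calmodulin-like genes 4 rose, CML37, CML38 (at least 21.7-fold), CML23 (5.52) and CML30 (3.74), with a median of 4.63, or 4.09 with CML38 at its bound. Of 11 tested genes of pattern-triggered immunity 8 rose and 2 fell, with a median of 2.06; STZ and the glutaredoxin gene GRX480 (4.71) rose most, and PUB24 stood at 0.51 and did not pass (0.012 without sorted-cell replicate 1 and 0.89 without replicate 2). Camera gave an adjusted p of 0.00381 for each of these lists, and an adjusted p of 0.716 with an estimated correlation, over a range of 0.00108 to 0.716 for each. Of 6 tested jasmonate genes, of 12 with a probe set, 3 rose and 3 fell: ORA47, JRG21 (at least 16.7-fold) and OPCL1 of jasmonate synthesis (2.90) were higher, and MYC3, a transcription factor gene of the jasmonate response, stood at -1.47 (camera adjusted p = 0.747, 0.965 with an estimated correlation).

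Of 65 plastid-encoded genes tested, 60 were higher and 5 did not pass, with a median log2 difference of 3.75, or 3.70 with 3 genes at their bounds. After rpoC1, matK and rpl20 the largest rise was that of accD, a subunit gene of acetyl-CoA carboxylase (6.73; 2 of 3 whole-root arrays above background). The ATP synthase gene atpB, at 2275 ± 326 in whole roots and 2869 ± 675 in sorted cells, and psbF of photosystem II, at 408 ± 221 and 1091 ± 926, did not pass. All 13 tested genes listed as mitochondrial, whose probe sets may also read a nuclear copy of mitochondrial DNA, rose, with a median of 4.06, among them cox1 of cytochrome oxidase, at 127 ± 64.6 in whole roots and 9774 ± 7004 in sorted cells, and orfX (6.12); nad1 (4.31; 2 of 3 whole-root arrays above background) stood at 2.79 without whole-root replicate 1. Both lists were drawn up after values of some organelle genes had been seen, so tests of them are not independent of these data. Camera gave an adjusted p of 1.39e-18 for the plastid and 3.6e-07 for the mitochondrial list, and an adjusted p of 0.716 for both with an estimated correlation. That correlation was 0.86 for the plastid and 0.76 for the mitochondrial list, against the preset 0.01. The ranges over all alternatives were 1.11e-22 to 0.716 and 6.71e-09 to 0.716. The control probe set of 25S ribosomal RNA was higher as well, from 342 ± 229 in whole roots to 7864 ± 1986 in sorted cells (n = 3 each). Among sorted cells it was lowest on replicate 1 (5690, against 9583 and 8318), where nad4 was highest (12296, against 3589 and 3234). Among whole roots 25S was lowest on replicate 1 as well (97.5, against 551 and 378). The plastid and mitochondrial medians were also lowest on that whole-root array. The control probe set of 5S ribosomal RNA, near the background level, went from 25.2 ± 14.0 to 44.4 ± 1.63.

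Nuclear genes of photosynthesis went the other way: of 11 tested, of 21 with a probe set, 7 fell and 4 did not pass, with a median of -1.50 (camera adjusted p = 0.0236). The adjusted p = 0.795 with an estimated correlation, and 0.0695 with the dimmest 60% of probe sets left out, over a range of 0.00583 to 0.795. RCA, the activase of Rubisco, stood at -3.09, TROL at -2.49, CHLM of chlorophyll synthesis at -1.97 and LHCB4.1 of the light-harvesting antenna at -1.64; 2 of 3 sorted-cell arrays read above background for RCA and LHCB4.1, and 1 for TROL. The call of TROL ended without whole-root replicate 2 (limma adjusted p = 0.0517, over a range of 0.00108 to 0.0517). Both tested genes of the green tissue list, RCA and LHCB4.1, fell over all genes and adjusted over the list alone.

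**Figure D2:**
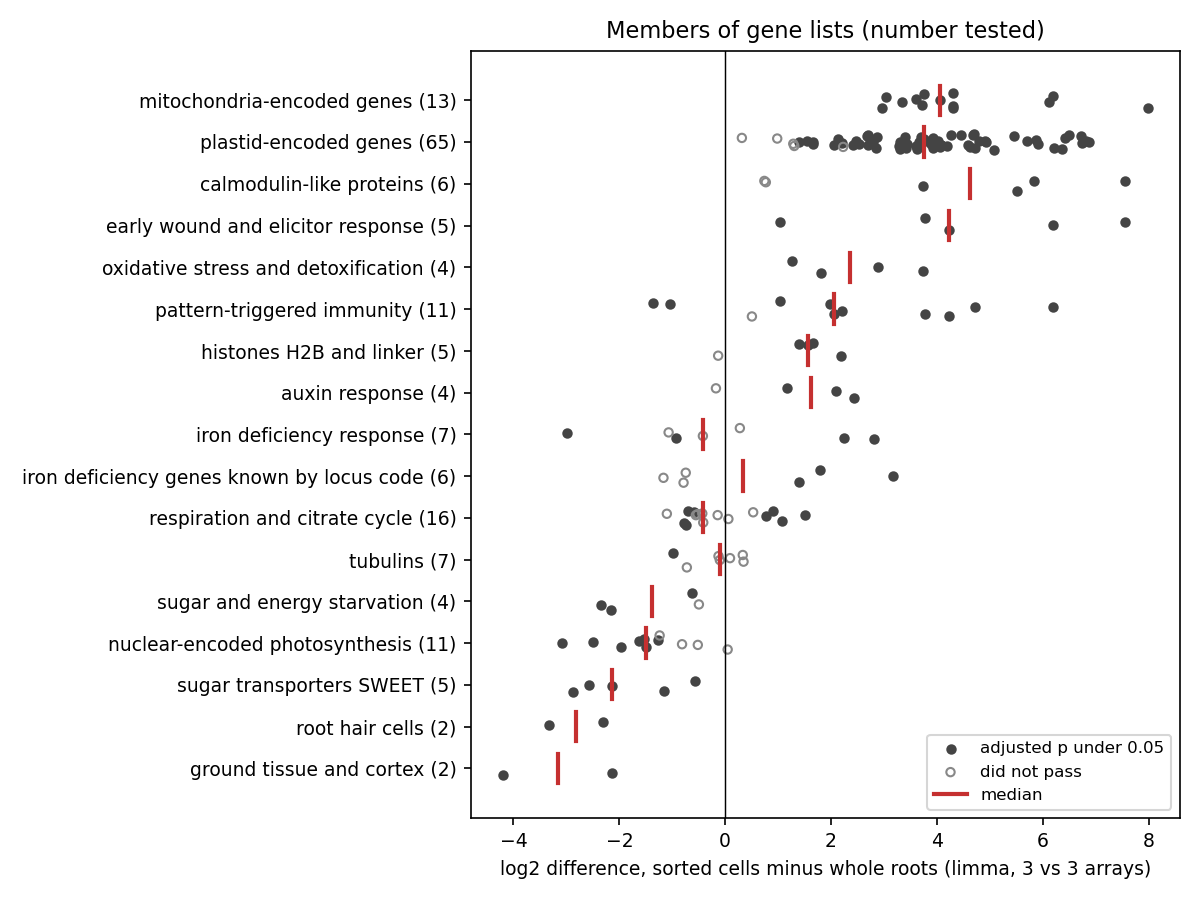
Each point is a tested member of a gene list, placed by its log2 difference (sorted cells minus whole roots, 3 arrays each); filled points passed limma's adjusted p of 0.05, open points did not, and red bars are medians. Plastid-encoded genes have a median of 3.75 and nuclear photosynthesis genes one of -1.50.

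Markers of single cell types moved apart, in lists of 1 or 2 tested genes that were too short for a list test. Both tested root hair markers, expansin genes of growing hairs, fell: EXPA18 from 1702 ± 214 to 172 ± 36.7 and EXPA7 from 1093 ± 154 to 223 ± 56.4. Both tested ground tissue markers, of 3 with a probe set, fell as well, JKD (-2.13) and AT1G09750 (-4.19, and -2.74 without sorted-cell replicate 1), each with 2 of 3 sorted-cell arrays above background. The root cap polygalacturonase gene AT1G65570 rose from 202 ± 18 to 4489 ± 2079, and the secondary wall gene GUT2 rose by 0.96 on the log2 scale. GSO1 of the endodermal barrier (-0.65) and LHW of the stele (-0.79) were lower, and AT4G28100 of the endodermis (0.52) and AGL42 of the stem cell niche (0.43, and 0.20 without whole-root replicate 1) did not pass over all genes. The calls adjusted over the list alone were the same for these 7 lists, except that AT4G28100 passed there. It also passed over all genes without sorted-cell replicate 2 (0.63) and with array quality weights (0.58). GSO1 lost its call with quantile normalization (limma adjusted p = 0.0593), median centring (0.0573), no variance trend (0.0504) and array quality weights (0.0637), without whole-root replicate 1, 2 or 3 (0.113, 0.1 and 0.106) and without sorted-cell replicate 2 (0.0932), over a range of 0.0135 to 0.113. LHW lost it with quantile normalization (limma adjusted p = 0.0657), without whole-root replicate 1 or 2 (0.097 and 0.055) and without sorted-cell replicate 3 (0.0776), over a range of 0.00527 to 0.097.

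The 5 tested SWEET sugar transporter genes, of 14 with a probe set, fell, with a median of -2.14 (camera adjusted p = 0.0214). The adjusted p = 0.716 with an estimated correlation, and with no filter on dim probe sets the median was -0.24 (adjusted p = 0.348), over a range of 0.00393 to 0.716. SWEET2 stood at -2.88, SWEET11 at -2.58, SWEET16 at -2.14 and SWEET17 at -1.15 on the log2 scale. In the sugar and energy starvation list 3 of 4 tested genes fell over all genes and 4 of 4 adjusted over the list alone (camera adjusted p = 0.0524, 0.276 with an estimated correlation). Its members belong to leucine breakdown, IVD (-2.35), MCCA (-2.15) and MCCB (-0.62), and to a kinase subunit, AKINBETA1 (-0.50, not passing over all genes). AKINBETA1 passed at -0.62 without sorted-cell replicate 3. MCCB lost its call without whole-root replicate 1, 2 or 3 (limma adjusted p = 0.0624, 0.121 and 0.0708) or sorted-cell replicate 3 (0.0673), over a range of 0.00324 to 0.121. The list passed without whole-root replicate 1 (-1.52, camera adjusted p = 0.0308), with no filter on dim probe sets (0.00606) and with fry (0.000741), over a range of 0.000741 to 0.276.

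Among early auxin genes, with 4 tested of 8 with a probe set, 3 rose over all genes and adjusted over the list alone, IAA29 (2.44), LBD16 (2.09) and GH3.3 (1.16), and WES1 stood at -0.17 and did not pass (camera adjusted p = 0.0938, 0.444 with an estimated correlation). GH3.3 lost its call without whole-root replicate 1 or 3 (limma adjusted p = 0.0725 and 0.074) or sorted-cell replicate 1 or 2 (0.0522 and 0.0712), and with array quality weights (0.0695), over a range of 0.00473 to 0.074. WES1 stood at 0.045 without sorted-cell replicate 2. Of the wall-loosening list EXPA4 (-1.85) fell, XTH19 (0.63) rose, and XTH18 (0.76) and XTH20 (0.69) did not pass, over all genes and adjusted over the list alone (camera adjusted p = 0.73). XTH19 lost its call without whole-root replicate 2 or 3 (limma adjusted p = 0.149 and 0.087) or sorted-cell replicate 3 (0.0732), and with median centring (0.0712), over a range of 0.00751 to 0.149, and XTH18 passed without sorted-cell replicate 2 (1.17), with quantile normalization (0.93) and with array quality weights (0.74). Without sorted-cell replicate 1 XTH18 stood at 0.45 and XTH20 at 0.43. The H2B histone genes HTB2 (2.18), HTB4 (1.67), HTB11 (1.57) and HTB1 (1.39) rose, with close sequences that may let their probe sets share signal, and HON4 (-0.13, and 0.032 without sorted-cell replicate 1) did not pass; this list had a camera adjusted p of 0.028. The adjusted p = 0.716 with an estimated correlation, and 0.0587 with no filter on dim probe sets, over a range of 0.00732 to 0.716.

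Single tested genes stood for other lists, 1 of 4 heat shock genes and 1 of 3 osmotic stress genes with a probe set. The chaperone gene AT5G48570 rose by 0.88 on the log2 scale and lost its call without whole-root replicate 3 (limma adjusted p = 0.0685, over a range of 0.00738 to 0.0685). COR47 of the cold and drought response rose by 1.03, but stood at 0.21 with quantile normalization (limma adjusted p = 0.38, and 0.0503 with no filter on dim probe sets, over a range of 0.0014 to 0.38) and at 0.67 without sorted-cell replicate 1. Both calls were the same adjusted over the list alone. COB of cellulose synthesis (-0.76) did not pass over all genes but passed adjusted over the list alone, and over all genes without sorted-cell replicate 3 (-1.04). It stood at -0.37 without sorted-cell replicate 1. Of 3 cell cycle genes AUR1, a mitotic kinase gene, rose by 0.90, and PRL (-0.14) and AUR2 (-0.60) did not pass, over all genes and adjusted over the list alone. AUR2 passed without sorted-cell replicate 2 (-0.89) and with array quality weights (-0.68), and PRL stood at 0.079 without sorted-cell replicate 1. Genes used as constant controls split: AT2G28390 stood at -0.78, PEX4 at 0.74 and GAPC2 at 0.66, all passing, and AT4G34270 at 0.26, not passing, over all genes and adjusted over the list alone (camera adjusted p = 0.587). GAPC2 stood at 0.04 with quantile normalization (limma adjusted p = 0.874) and lost its call with no filter on dim probe sets (0.0874) and without whole-root replicate 1 or 3 (0.0633 and 0.0935), over a range of 0.00251 to 0.874. AT2G28390 and PEX4 lost theirs without whole-root replicate 2 (limma adjusted p = 0.0518 and 0.0536, over ranges of 0.00711 to 0.0518 and 0.00556 to 0.0536), and AT4G34270 passed without sorted-cell replicate 3 (0.57) and stood at 0.11 without replicate 1.

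For genes known to be induced by iron deficiency, rises and falls stood side by side. AT3G13610, which codes for an enzyme of coumarin synthesis, fell from 972 ± 443 in whole roots to 122 ± 54.4 in sorted cells (log2 difference -2.98, SE 0.43; limma adjusted p = 0.000482). AT1G74770, for a ubiquitin ligase of iron sensing, stood at -0.93 and passed. AT1G47400, for a small peptide of the iron deficiency signal, rose by 2.81 and BHLH101, a transcription factor gene of iron uptake, by 2.25, each with 2 of 3 whole-root arrays above background. PYE (0.28), the β-glucosidase gene BGLU42 (-0.42) and AT3G12900, a gene of coumarin synthesis (-1.07; 2 of 3 arrays of each group above background), did not pass. Of 36 listed iron deficiency genes 7 had a probe set in the annotation used, and the others, among them IRT1, FRO2 and FIT, were not analysed here. These 7 tested members thus had 2 higher, 2 lower and 3 not passing, over all genes and adjusted over the list alone, with a median of -0.42 and a camera adjusted p of 0.884 (0.953 with an estimated correlation). Of all tested probe sets 55.4% were called, so the calls among these 7 do not by themselves set iron genes apart. The storage and sufficiency list had SAPX alone, at -0.09 and not passing (limma adjusted p = 0.721). SAPX stood at 0.0086 without whole-root replicate 3.

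Of 6 further iron deficiency genes tested, known by locus code, AT3G61930 rose by 3.17, AT3G06890 by 1.79 and AT5G05250 2.64-fold, and AT3G07720 (-1.17), AT5G38820 (-0.74) and AT1G73120 (-0.79; 2 of 3 sorted-cell arrays above background) did not pass. The list had a median of 0.33, which was -0.36 without whole-root replicate 3 (camera adjusted p = 0.587, and 0.942 without that array, over a range of 0.39 to 0.965).

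The whole-root arrays were not alike in these genes. AT3G12900 read 504, 415 and 3.34 on whole-root replicates 1, 2 and 3, AT1G47400 read 50.3, 52.6 and 3.45, and AT3G07720 read 2356, 1789.7 and 390.3. All 7 members of the fixed list and all 6 genes known by locus code were lower on replicate 3 than on both others. Without whole-root replicate 3 the median of the fixed list was -0.92 (camera adjusted p = 0.264, over a range of 0.264 to 0.954), AT3G12900 stood at -3.43, AT3G07720 at -1.96, AT5G38820 at -1.54, AT1G73120 at -1.55 and BGLU42 at -0.92, all passing, AT1G47400 at 1.51 and BHLH101 at 1.18, still passing, and PYE at -0.08. Without replicate 1 or 2 of whole roots the list's median was 0.18 or 0.04, which were the values of AT3G12900 there. BGLU42 stood at -0.099 without whole-root replicate 1.

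Some of these calls ended when 1 array was left out, most with differences near those reported. AT1G74770 lost its call without whole-root replicate 1 (-0.78, limma adjusted p = 0.0783) or 2 (-0.76, 0.084), over a range of 0.00439 to 0.084. BHLH101 lost it without sorted-cell replicate 2 (log2 difference 1.93, limma adjusted p = 0.114) or 3 (2.33, 0.0865), over a range of 0.0117 to 0.114. AT1G47400 lost it without the same arrays (2.42 and 2.94, limma adjusted p = 0.101 and 0.0744, over a range of 0.00685 to 0.101). AT5G05250 lost it without sorted-cell replicate 2 (log2 difference 1.17, limma adjusted p = 0.0886), with array quality weights (1.22, 0.0576) and, with a smaller difference, without whole-root replicate 3 (0.82, 0.0674), over a range of 0.00447 to 0.0886.

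**Figure D3:**
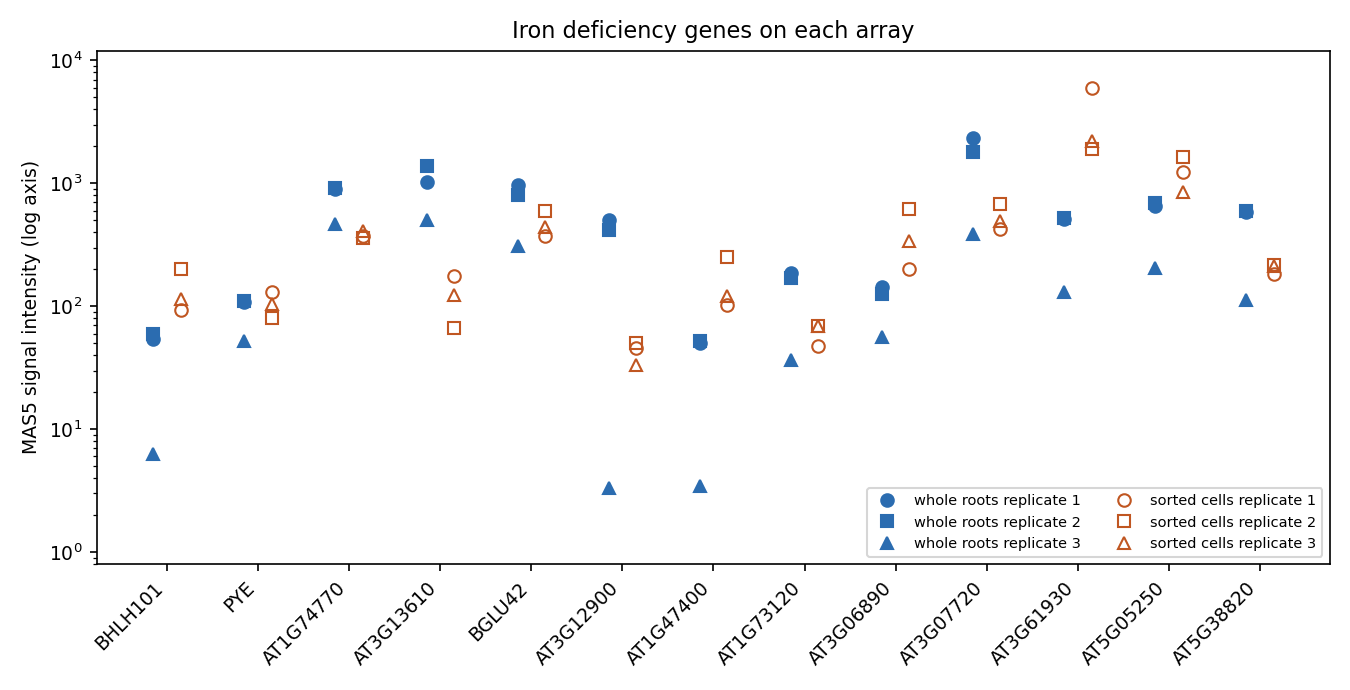
MAS5 signal intensity (log axis) of 13 iron deficiency genes on each of the 6 arrays, with filled symbols for whole roots, open symbols for sorted cells and a shape for each replicate number. Whole-root replicate 3 lies under replicates 1 and 2 for every gene drawn, as for AT3G12900 at 3.34 against 504 and 415.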

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

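The tests of the organelle transcripts and of the 3′ skew, and those of the counts of genes over other splits, were chosen only after the values had been seen. The signals given first come from control probe sets outside the comparison of genes, and each was higher on all 3 sorted-cell arrays than on all 3 whole-root arrays (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). The 25S ribosomal RNA probe set was higher by 4.82 on the log2 scale, and that of 5S ribosomal RNA by 0.96, near the background level. The mean of 18 hybridization spike-in probe sets was higher by 1.61, with 2310, 1413 and 853 on sorted-cell replicates 1, 2 and 3 against 436 to 476 on whole roots. The log2 difference between 3′ and 5′ probe sets was larger in sorted cells by 2.64 for actin, 2.90 for GAPDH, 1.2 for a second pair of GAPDH probe sets and 0.73 for ubiquitin. Outside this rule, a second pair of actin probe sets gave the same 5.13 in both groups and a second ubiquitin pair 2.64 in whole roots and 3.03 in sorted cells, with overlapping arrays. The 5′ probe set of that actin pair was dim, at 75.8 in whole roots and 87.2 in sorted cells.

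In sorted cells 60 of 65 plastid genes tested, 13 of 13 listed as mitochondrial and 25S ribosomal RNA were higher. Green tissue among the sorted cells would bring nuclear photosynthesis transcripts too, but these had a median of -1.50, with RCA at 369 in whole roots and 45.1 in sorted cells. This goes against green tissue but does not exclude it. The list was drawn up after some organelle values had been seen, and its camera adjusted p was 0.795 with an estimated correlation. The 3′ skew, weighed below, could lower such transcripts too. Scaling of the arrays would have to lower the rise with quantile normalization, and this left the plastid median at 3.58. The arrays already had nearly the same trimmed mean, which favoured a small change in advance, so this does not exclude scaling. The spike-in probe sets were higher in sorted cells by 1.61, less than the plastid median of 3.75. Labelling of more RNA without poly(A) tails in the sorted-cell samples needs a rise of ribosomal RNA, and the 25S probe set was higher by 4.82 but the dim 5S probe set by only 0.96. Among sorted-cell replicates 1, 2 and 3 the orders differed: plastid genes lay at a median of 4.83, 3.09 and 3.01 above the whole-root mean and 25S at 4.38, 5.13 and 4.93. Among whole-root replicates 1, 2 and 3 the order was the same. Plastid genes lay there at -1.01, 0.66 and 0.39 from that mean and 25S at -1.48, 1.01 and 0.47. More labelling of such RNA thus stays open and is not settled by 25S. A change of organelle RNA in the cells themselves was not tested and stays open as well, as each group had its own preparation.

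The falls were weighed against the 3′ skew as their whole cause. The 4187 probe sets called lower had a median difference from whole roots of -1.36 on sorted-cell replicate 1, where the mean skew over 6 pairs of control probe sets exceeded that of whole roots most (2.08), and -1.19 on replicate 3, where it did least (0.738). The quotient of the falls was 0.874 and that of the skews 0.354. This decides nothing, since the probe sets were called over all 3 sorted-cell arrays, which favours like falls on each. The skew and an untested effect of the digestion on the cells both stay open.

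The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. In 1 of the 10, the real one, limma called 7564 probe sets (3377 higher and 4187 lower). The highest of the others was 0, with 21 to 227 probe sets at an unadjusted p under 0.05 against 8374 in the real split. Every other split has arrays of both groups on each side, so the group difference widens the spread within a side. Few calls there were favoured in advance, and 0 against 7564 decides nothing. As many fixed lists as the real 2 were called in 5 of the 10 splits, and the highest other count was 3. For the iron deficiency list 7 of the 10 splits gave a median at least as far from 0 as the real -0.42, and the farthest was -1.06.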

How the results depend on the processing

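Array quality weights were chosen after seeing the data. Across alternatives the count of differing probe sets ranged from 5388 (at least 2-fold) to 8562 (array quality weights), within 1.5 times the 7564 reported. It was 5976 to 8271 with 1 array left out. With quantile normalization 6881 of the 7564 were called again in the same direction. The difference of 7 of the 7564 changed sign there, whether or not it passed. The labels do not say whether the replicate numbers pair the samples. Deviations of same-numbered arrays from their group means correlated at -0.29, -0.16 and -0.04. With 3 arrays per group, whose deviations sum to 0, this cannot show whether the numbers pair them. With the replicate block 6815 probe sets differed, and MCCB, XTH19, GSO1, ILR3, POLD3 and the xyloglucan transferase list lost their call. Of 131 called genes that the rule selects, 101 kept their call under all alternatives run and 30 lost it under at least 1: BHLH101, AT1G74770, AT1G47400, AT5G05250, ILR3, AT5G48570, COR47, MCCB, GH3.3, XTH19, GSO1, LHW, AT2G28390, PEX4, GAPC2, GSTU28, ATG8G, ATG8H, Hop3, TROL, cICDH, CYTC-1, ICDH, GH9B8, TUB5, POLD3, HBT, ASF1B, NRPA2 and ALPHA-VPE. All 10 lists called by camera lost the call with an estimated correlation. Low signal sets a limit: between 60.9% and 79.2% of probe sets on an array read above the brightest bacterial control. That control read 57.4, 36.3 and 14.3 on sorted-cell replicates 1, 2 and 3 and 10.4 to 16.8 on whole roots. The median of the bacterial controls was 4.07 to 7.37 in sorted cells and 1.25 to 2.28 in whole roots. Dim signals thus met a higher floor on sorted-cell replicates 1 and 2, which bears on dim rises and falls.

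Fixed lists past the threshold numbered 2, against 4 with no filter on dim probe sets, 0 with camera's estimated correlation and 5 with fry, which asks another question; with 1 array left out the count was 2 to 3. The wound list (4.22) and the detoxification list (2.35) lost the call with an estimated correlation. The sugar starvation list passed with no filter and with fry (-1.39 in both) and ranged from -1.52, passing without whole-root replicate 1, to -1.27 with 1 array left out. The auxin list passed with no filter (1.51) and with fry (1.62), and the reference genes passed with fry (0.46). Of 26 lists added later 8 passed, and 15 with fry. The cause was not tested.

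The median of the iron deficiency list ranged from -0.92 without whole-root replicate 3 to 0.18 without replicate 1, with 0.04 without replicate 2, so its sign depends on these arrays; it passed in no setting. With 1 array left out AT3G12900 ranged from -3.43 to 0.18, PYE from -0.079 to 0.46 and the list of iron genes known by locus code from -0.36 to 0.69.

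Other values that changed sign had not passed as reported, and the cause was not tested. With quantile normalization they were the folding list of the endoplasmic reticulum (0.059), cochaperones (0.026), SAPX (0.036), WES1 (0.018), PRL (0.036), BOB1 (0.034), EXPA9 (0.0057), HON4 (0.046) and PYK10 (-0.62, passing). With array quality weights they were glutathione transferases and ATGSTF13 (both -0.069), the folding list (0.22), tubulins (0.17), SAPX (0.011), AT4G34270 (-0.030) and GSTU23 (-0.36). With no filter cochaperones stood at 0.050 and expansins at 0.067, and with 60% left out cochaperones at 0.054 and cell division at 0.13. With 1 array left out the folding list ranged from -0.18 to 0.16, cochaperones from -0.19 to 0.031, tubulins from -0.19 to 0.10, SAPX from -0.20 to 0.0086, WES1 from -0.43 to 0.045, PRL from -0.36 to 0.079, GSTU23 from -0.23 to 0.42, Hop2 from -0.067 to 0.21, BOB1 from -0.32 to 0.055, EXLB1 from -0.19 to 0.54, TUB9 from -0.25 to 0.062 and HON4 from -0.32 to 0.032.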

Other observations

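The test of further iron deficiency genes was set before their values were looked at, and that of the fixed iron list was chosen after. Other gene families of the annotation held rises, falls or both, and counts of genes here are of those tested. Of all tested probe sets 55.4% were called, so a count at or under that share is not particular to a family. Of 27 UDP-glycosyltransferase genes 10 fell and 4 rose, with UGT73B1 (-3.22) and UGT71C1 (-3.06) against UGT73B4 (2.89) and UGT71B5 (2.55); 2 of 3 arrays of the dimmer group read above background for UGT73B1 and UGT71B5, as for EXPB3, OSM34 and ALPHA-VPE. Of 12 expansin genes 5 fell, among them EXPB3 (-2.45), and 2 rose, among them EXLA1 (2.33). In the GH9 endoglucanase family GH9C1 fell (-3.11) and GH9B6 rose (2.82), and in the TBL family of wall acetylation 7 of 17 genes rose, led by TBL45 (2.25), and 1 fell. Of 8 cold and dehydration genes 3 fell, OSM34 (-4.42), TIL (-2.27) and DI19 (-1.44), and 2 rose, among them HVA22C (1.26). The vacuolar protease gene GAMMA-VPE fell from 3182 ± 103 to 405 ± 69.0 (n = 3 each), and ALPHA-VPE (-1.77) stood at -1.18 without sorted-cell replicate 2 and lost its call without replicate 3 (limma adjusted p = 0.0549, over a range of 0.000139 to 0.0549). The lists of this paragraph had camera adjusted p-values of 0.205 to 0.981, except the proteases, whose list was too short to test.

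In the system of ER bodies and the root β-glucosidase, the lectin genes JAL22 (-4.99) and JAL33 (-1.33) fell, JAL22 with 2 of 3 sorted-cell arrays above background, whereas JAL34, at 8134 ± 735 and 7327 ± 1037, and PYK10, at 7299.6 ± 746 and 7826 ± 944, did not pass (n = 3 each). With quantile normalization JAL34 stood at -0.92 and PYK10 at -0.62, both passing; without sorted-cell replicate 1 they stood at -0.058 and 0.20. Of 16 genes of respiration 4 rose and 4 fell, with CYTC-2 at 1.51, and cICDH (1.07) and CYTC-1 (0.90) stood at 0.23 and 0.22 with quantile normalization, not passing; of the falls ICDH (-0.78) lost its call without whole-root replicate 1 or 3 (limma adjusted p = 0.0518 and 0.0705) or sorted-cell replicate 3 (0.0528), over a range of 0.00354 to 0.0705. Of 7 aldehyde dehydrogenase genes 4 fell, led by ALDH7B4 (-1.17), and ALDH3F1 rose (2.01). Of 9 glutathione transferases 4 rose and 1 fell, GSTU28 (-1.32), which lost its call without whole-root replicate 2 (limma adjusted p = 0.0661) or sorted-cell replicate 3 (0.0626), over a range of 0.000331 to 0.0661. Of 10 autophagy genes ATG8C (1.47), ATG8G (1.05) and ATG8H (0.96) rose and ATG3 (-1.15) fell. ATG8G lost its call without whole-root replicate 1 or 2 (limma adjusted p = 0.0545 and 0.0502, over a range of 0.011 to 0.0545). ATG8H lost it without whole-root replicate 1, 2 or 3 (limma adjusted p = 0.0674, 0.0764 and 0.0715) or sorted-cell replicate 3 (0.0555), over a range of 0.00352 to 0.0764, and stood at 0.60 without sorted-cell replicate 1. Of 14 genes of the endoplasmic reticulum 3 rose and 5 fell, led by DER2.2 (-1.79). Of 9 cochaperones 1 rose, Fes1A, and 1 fell, Hop3 (-0.80, without a call when whole-root replicate 2 was left out, limma adjusted p = 0.0553, over a range of 0.00692 to 0.0553), and of 9 RNA polymerase subunits 4 rose, led by NRPB6A (1.33), and 2 fell, NRPC2 (-1.18) and NRPA2 (-1.09). NRPA2 lost its call with quantile normalization (limma adjusted p = 0.0676), with no variance trend (0.0536), without whole-root replicate 1, 2 or 3 (0.0887, 0.0996 and 0.0838) and without sorted-cell replicate 1 or 3 (0.0675 and 0.111), over a range of 0.00157 to 0.111; it stood at -0.67 without sorted-cell replicate 1. Of 7 tubulins 1 fell, TUB5 (-0.99), which stood at -0.61 without sorted-cell replicate 1 and lost its call without whole-root replicate 1, 2 or 3 (limma adjusted p = 0.0761, 0.0877 and 0.0501, over a range of 0.00707 to 0.0877). Adjusted over the list alone, 0 tubulins passed. Of 16 genes of cell division 1 rose and 3 fell, POLD3 (-1.01; 2 of 3 sorted-cell arrays above background), HBT (-0.79) and ASF1B (-0.79), and 0 passed adjusted over the list alone. All 3 falls lost their call with quantile normalization (limma adjusted p = 0.0559, 0.051 and 0.0598) and without whole-root replicate 1 (0.149, 0.0712 and 0.0839) or 3 (0.067, 0.0594 and 0.105). POLD3 and HBT lost it without whole-root replicate 2 (limma adjusted p = 0.0625 and 0.0596), POLD3 and ASF1B without sorted-cell replicate 3 (0.119 and 0.0501), and POLD3 with no filter on dim probe sets (0.0559) and without sorted-cell replicate 1 (0.07). The ranges were 0.00492 to 0.149 for POLD3, 0.0157 to 0.0712 for HBT and 0.0142 to 0.105 for ASF1B. Of 5 bHLH partners of iron regulators bHLH115 fell (-1.30) and ILR3 rose (0.74, without a call when whole-root replicate 1 or 3 was left out, limma adjusted p = 0.0957 and 0.101, or sorted-cell replicate 3, 0.0555, over a range of 0.0117 to 0.101). The lists named so far in this paragraph had camera adjusted p-values of 0.276 to 0.993. A list of 6 xyloglucan transferase genes was called by camera (adjusted p = 0.039), with XTH21 (2.11), XTH16 (1.27) and XTH19 (0.63) higher. Its adjusted p = 0.716 with an estimated correlation, 0.057 without whole-root replicate 3 and 0.0789 without sorted-cell replicate 1, over a range of 0.00214 to 0.716.

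Whole-root replicate 3 read low in genes induced by iron deficiency, with medians of -1.50 on the log2 scale against the other replicates over the 7 of the fixed list and -2.14 over the 6 known by locus code. An array-wide shift would move other genes too, but random lists matched on mean intensity had a median of 0.033. The median of the fixed list lay at percentile 0.01 of 10000 such lists, the smallest they can give. Over all tested probe sets the median deviation was 0.0043. This median and that of the random lists add little, since the arrays had been scaled to nearly the same trimmed mean. The percentile shows only that the fixed list lay under random genes of like intensity on that array. A candidate explanation is a weaker iron deficiency response in the roots of that sample, which predicts low values in further genes of this kind. Of 7 such genes 3 were tested, with a median at percentile 0.17 of random lists: AT3G58060 read 140, 170 and 8.62 on whole-root replicates 1, 2 and 3, the last under the background level, AT3G18560 read 129, 137 and 76.9, and AT1G18910 read 583, 551 and 476. Random lists were drawn gene by gene, whereas the genes of the fixed list varied together, with an estimated correlation of 0.80. Both percentiles, 0.01 and 0.17, are thus too extreme as measures of chance. The labels give the same treatment for all 3 replicates, so what set this sample apart is open, and a wrong label was not tested.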
